A study of Mus musculus with 8 samples.

How the data were processed

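Single-cell RNA libraries were measured from 8 samples of mouse bone marrow. Per the labels, donor cells carrying CD45.2 and a GFP barcode vector were sorted by FACS as haematopoietic stem cells (HSC) or as MPP3, a multipotent progenitor population biased towards myeloid cells. The genotype was control or Tet2 knockout. Poly-A RNA was reverse transcribed with the 10x Genomics 3′ chemistry of version 3.1, which tags each molecule with a unique molecular identifier (UMI). The deposited matrices hold whole-number UMI counts per gene and cell barcode, with no normalization, and 1 filtered matrix stands for 1 library. Cell Ranger 6 and the mm10 build are named in the submitters' processing notes. The counting options and the annotation release are not stated there. Gene coordinates were taken from GENCODE M21 (mm10, GRCm38), in which 32235 of the 32285 gene identifiers were found.

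The matrices held 40136 barcodes and 609852442 UMIs. Barcodes with fewer than 1000 UMIs or fewer than 500 genes (2615) or with more than 10% mitochondrial UMIs (5204) were left out, which kept 32317 cells and 592687510 UMIs. Scrublet was run with an expected doublet rate of 6% and marked 20 of 37521 cells (0.0533%). This lay under the minimum of 0.5% set for using it, so all marked cells were kept and their removal was run as an alternative.

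Counts were summed over the kept cells of each library. Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood, TMM normalization, filterByExpr) in R 4.3.3, in a single fit over the 8 libraries with 1 coefficient per group. The fit had 4 residual degrees of freedom, a common biological coefficient of variation of 0.231 and a median prior of 4.37 degrees of freedom. The 16239 genes tested were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. The contrasts were knockout against control in HSC and in MPP3, MPP3 against HSC in control and in knockout, and the interaction, defined as the genotype effect in MPP3 minus that in HSC. Values are CPM, counts scaled to TMM-adjusted library sizes, given as mean ± SD over 2 libraries, and log2 fold changes with their SE. DESeq2 1.42.0 was run beside edgeR. A 2 against 2 comparison allows 6 splits, so an exact two-sided permutation test cannot go below p = 0.3333 and none is reported.

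A total of 35 gene lists were tested in each contrast with camera (limma 3.58.1, inter-gene correlation preset at 0.01) where at least 5 members were tested. They cover stem and blood cell types, cell cycle, stress, signalling and metabolism, and each is named with its values in the results. Adjustment was over the lists of a contrast. Camera with an estimated correlation was run beside it, as were fry's directional and mixed tests and a count of members adjusted over the list alone. Fry compares no list with other genes.

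Cells were clustered in 1 graph with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, no integration). A cluster was named where at least 3 markers of 1 class stood among its 50 genes with the highest fold over the other cells, with a pseudocount of 20 CPM and no competing class. Class shares carry 95% exact binomial intervals, which cover counting error alone, and were tested with edgeR on cells per class. The share of cells with G2/M transcripts was the share with at least 3 UMIs over the G2/M list after thinning every cell to 4000 UMIs. Cells below that depth were left out. Genotype was also tested within a class where every library of the contrast held at least 100 of its cells.

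Genes named in the text were taken by a fixed rule. It took Tet2, the called genes with the 10 highest and 10 lowest folds (5 each way for the interaction) among those with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, and the 4 members of each list with the smallest p. Mitochondrial and predicted genes were left out, and the overlap rule was not applied to the interaction. Some genes that the rule took are not reported here. Genes outside the rule are marked as chosen after their values were seen. The lists, the rule, the contrasts, the thresholds, the cluster naming and most other settings were fixed before the data were examined. Sex marks, histone genes and the settings named as added in the closing section were chosen afterwards. A cell was marked female with at least 2 Xist UMIs and no Y-linked UMI, and male with at most 1 Xist UMI and at least 1 UMI of Ddx3y, Eif2s3y, Kdm5d or Uty. Where a group held no counts of a gene, its fold and the medians marked as at the bound were computed against a floor of 3 counts over the group. Medians without that mark are of fitted folds. Folds from 1 to 3 counts carry exact Poisson intervals.

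The procedure was run on simulated data with 200 genes changed 1.5, 2 or 4-fold in equal parts. At 4-fold, 84.8% of changed genes were recovered for genotype in HSC, 92.4% in MPP3, 86.4% and 90.9% for the populations in control and knockout, and 72.7% for the interaction. At 2-fold the shares were 19.4%, 37.3%, 37.3%, 32.8% and 5.97%. At 1.5-fold they were 5.97%, 4.48%, 5.97%, 0% and 0%. Real recovery may be lower: Hist1h2ab (-2.24 in MPP3) was not called. Between 6 and 9 unchanged genes were called in each of these contrasts, and no changed gene was given the wrong sign. The comparison of sex marks recovered 88.1%, 94.0% and 98.5% at these folds, with 21 unchanged genes called.

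Alternatives included other scaling, models, cell filters and clusterings, and each library left out in turn. The labels give replicate numbers but do not state that libraries of the same number share an animal, nor that replicates come from separate animals. The p-values therefore measure spread between these libraries. Replicates of a group were checked against being copies of each other, with a chi-square per degree of freedom of 40.7, 196, 73.6 and 197 for control HSC, control MPP3, knockout HSC and knockout MPP3 over genes with at least 50 counts. The lineage barcodes carried by the GFP vector are not analysed here.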

Results

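Transplanted donor cells were profiled from mouse bone marrow 13 months after transplantation, as sorted HSC and as sorted MPP3 progenitors, in a control and a Tet2 knockout genotype. Tet2 is a dioxygenase that oxidises methylated cytosine in DNA and is often mutated in clonal haematopoiesis. Tamoxifen had been given 1 month after transplantation to let Cre excise Tet2. There were 2 libraries in each of 4 groups. The comparisons ask what the loss of Tet2 changed in each population, what sets MPP3 apart from HSC in each genotype, and whether the genotype effect differed between the populations.

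After filtering, control HSC libraries 1 and 2 held 2132 and 1802 cells, with 32804079 and 28495726 UMIs in total and medians of 14426 and 14449 UMIs per cell. Control MPP3 libraries held 4833 and 3753 cells, 101101193 and 86028338 UMIs, and medians of 17385 and 19932 UMIs. Knockout HSC libraries held 1178 and 3875 cells, 15061288 and 58572867 UMIs, and medians of 11032 and 15835 UMIs. Knockout MPP3 libraries held 7125 and 7619 cells, 132982418 and 137641601 UMIs, and medians of 14474 and 14739 UMIs. Median genes per cell lay between 3416 and 4648, and median mitochondrial shares between 2.11% and 4.05%. In knockout HSC 2, 1327 cells fell in a shallow cluster with a median of 1955.5 UMIs.

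Tet2 transcripts (ENSMUSG00000040943, mm10 chromosome 3, 133463679 to 133545139, minus strand) were present in all 8 libraries. They reached 13.7 ± 0.478 CPM (SD, n = 2) in control HSC and 21.6 ± 1.98 CPM in knockout HSC, and 18.2 ± 3.71 CPM in control MPP3 and 22.8 ± 2.43 CPM in knockout MPP3. The log2 fold change of knockout over control was 0.65 (SE 0.18) in HSC, with an adjusted p of 0.811, and 0.33 (SE 0.18) in MPP3, with an adjusted p of 1. The exons excised are not stated, and a 3′ tag can lie outside an excised part, so these counts check nothing about the excision.

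In control mice, MPP3 cells carried myeloid, lymphoid and cell cycle programmes that were lower in HSC, and HSC carried stem cell, platelet and ageing genes that were low in MPP3. The granule enzyme myeloperoxidase, Mpo (chromosome 11, 87793581 to 87804413, plus strand), rose from 8.98 ± 2.85 CPM in HSC to 1213 ± 691 CPM in MPP3, a log2 fold change of 7.08 (SE 0.99, adjusted p = 0.00251). Von Willebrand factor, Vwf (chromosome 6, 125546774 to 125686679, plus strand), fell from 68.3 to 1.34 CPM, a log2 fold change of -5.67 (SE 0.40, adjusted p = 0.000165). Of 16239 genes tested with edgeR, 1460 rose and 1763 fell in MPP3. Of these 3223 genes, 776 rose and 1375 fell at least 2-fold. DESeq2 called 3785. Without control HSC 1, control HSC 2, control MPP3 1 or control MPP3 2, edgeR called 1384, 1318, 1972 and 1577 genes.

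HSC identity genes fell in control MPP3, with 24 of 30 members lower, none higher, 6 not passing and a median log2 fold change of -2.02 (adjusted p = 8.93e-30 by camera, 0.0809 with an estimated correlation). Among them were Slamf1, which encodes CD150 (chromosome 1, 171767127 to 171801184, plus strand; 34.7 to 1.66 CPM, log2 fold change -4.38, SE 0.25, adjusted p = 8.14e-05), the transcription factors Mllt3 (-2.56) and Tcf15 (-3.00), and the junctional adhesion molecule Jam2 (-3.92). Genes of the HSC ageing list fell further, with 24 of 30 lower and 1 higher, a median of -3.63 and an adjusted p of 3.12e-45. They included the secreted chaperone clusterin, Clu (-5.37, SE 0.25, adjusted p = 3.54e-05), Sult1a1 (-5.12), and Vwf. Megakaryocyte and platelet genes fell with a median of -2.25, 16 of 19 lower and none higher (adjusted p = 1.94e-30). Cavin2, a coat protein of caveolae (chromosome 1, 51289126 to 51302960, plus strand), went from 125 to 0.551 CPM (log2 fold change -7.82, SE 0.30, adjusted p = 1.69e-05), and the platelet receptor gene Treml1 had a log2 fold change of -3.88. The tight junction gene Cldn5 (-8.65), Tm4sf1 (-6.62) and the angiomotin family gene Amotl2 (-6.28) were among the steepest decreases. Self-renewal and leukaemia regulators fell as a list (8 of 21 lower, none higher, median -0.54, adjusted p = 0.000444, 0.508 estimated), with Prdm16 at -1.79, Hoxb5 at -2.24 and Mycn at -2.97. Adjusted over the list alone, 26 HSC identity genes, 27 ageing genes, 17 platelet genes and 10 self-renewal genes were lower, and 2 ageing genes and 1 self-renewal gene were higher. Slamf1, Cd34 (42.6 to 398 CPM, log2 fold change 3.22), Cd48 (4.46) and Flt3 encode surface proteins that are widely used to sort these populations. The labels do not say which markers defined the gates. Whether these 4 genes reflect the gates or a difference beyond them therefore cannot be told.

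Among genes higher in control MPP3, myeloid granule genes had a median of 3.13, with 15 of 18 up and none down (adjusted p = 4.06e-19, 0.0641 estimated). Cathepsin G, Ctsg (chromosome 14, 56099881 to 56102574, minus strand), had a log2 fold change of 6.39 (SE 1.04, adjusted p = 0.00443), and neutrophil elastase, Elane, one of 5.35 (SE 1.47, adjusted p = 0.0363). The Elane call ended without control HSC 1 (5.18), control HSC 2 (5.53), control MPP3 2 (4.70) or knockout MPP3 2 (5.35). Myeloid regulators (7 of 20 up, none down, median 0.65, adjusted p = 0.000788, 0.261 estimated) included Cebpa at 4.64, a driver of granulocyte and monocyte fate, and Irf8 at 2.95, a factor of monocyte and dendritic development. Without control MPP3 1 or 2 their median was 0.98 or 0.27. Monocyte and macrophage genes rose with a median of 2.08, 10 of 16 up and none down (adjusted p = 1.18e-07, 0.194 estimated). Basophil and mast cell genes had 8 of 12 up and 1 down and a median of 5.31, or 4.22 with genes at 0 in HSC set to their bound (adjusted p = 7.21e-10, 0.0951 estimated). Mcpt8, a basophil protease, had no UMI in either HSC library and 25.4 CPM in MPP3, at least 503-fold higher against a floor of 3 counts over the group, and the mast cell carboxypeptidase Cpa3 had a log2 fold change of 4.39. Eosinophil genes had 3 of 6 up and a median of 3.85, or 2.97 at the bound (adjusted p = 0.0177, 0.232 estimated), and a median of 2.41 without control MPP3 2. Lymphoid priming genes rose too, with 7 of 18 up and none down, a median of 1.87 (1.11 without control MPP3 1, or 0.82 at the bound, and 3.58 in male-marked cells) and an adjusted p of 9.29e-15. The chromatin organiser Satb1 (chromosome 17, 51736187 to 51833290, minus strand) had a log2 fold change of 4.74 (SE 0.19, adjusted p = 1.69e-05), the cytokine receptor Flt3 one of 3.86, and Cd52 one of 3.31. Dntt, which adds nucleotides at antigen receptor junctions, was at 83.4 and 25.3 CPM in the MPP3 libraries and at 0.0959 and 0 CPM in the HSC libraries. Tespa1 (4.93) and the chemokine gene Ccl9 (4.996, SE 0.31, adjusted p = 0.000105) rose too. With p adjusted over the list alone, 16 granule, 9 regulator, 14 monocyte, 10 basophil, 4 eosinophil and 11 lymphoid genes were higher.

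All 30 G2/M genes rose in control MPP3 (median 1.73, adjusted p = 1.94e-30, 0.194 estimated), as did 27 of 30 S-phase genes (median 1.19, adjusted p = 9.49e-24, 0.194 estimated). Ube2c, a ubiquitin-conjugating enzyme of the anaphase promoting complex, had a log2 fold change of 2.06, the mitotic kinase Cdk1 one of 1.64, survivin, Birc5, one of 1.69, and thymidylate synthase, Tyms, one of 1.30. Quiescence genes and CDK inhibitors had 2 of 18 up, 6 down and a median of -0.34 (adjusted p = 0.0158, 0.508 estimated). The CDK inhibitor Cdkn1c was at -2.58, necdin, Ndn, at -3.93 and Klf9 at -1.45. The DNA methylation machinery had 5 of 15 up, none down and a median of 0.41 (adjusted p = 0.00242, 0.508 estimated), with Uhrf1, which recruits maintenance methylation to replicating DNA, at 1.33 and isocitrate dehydrogenase Idh2 at 0.96. Interferon response genes were lower (1 of 37 up, 13 down, median -0.42, adjusted p = 0.000205, 0.558 estimated), with Slfn2 at -3.13, while Ifi27l2a was at 2.13. That median was -0.25 without control HSC 2 and -0.69 without control MPP3 2. Homing and adhesion receptors had 5 of 15 up, 5 down and a median of 0.48 (adjusted p = 0.00809, 0.194 estimated), which was 0.29 without control HSC 1 and -0.05 without control MPP3 2. Oxidative phosphorylation had 3 of 36 up, none down and a median of 0.19 (adjusted p = 0.0488, 0.903 estimated). That call ended without control HSC 2 (0.07), control MPP3 1 (0.13), knockout HSC 1 or knockout HSC 2 (both 0.20) and with the replicate block (0.20), and the median was 0.35 and 0.30 without control HSC 1 and control MPP3 2. With p adjusted over the list alone, 30 G2/M, 29 S-phase, 3 quiescence, 5 methylation, 2 interferon, 6 homing and 0 oxidative phosphorylation genes were higher, and 7 quiescence, 14 interferon and 6 homing genes were lower.

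Of the 17 lists that passed in control mice, 11 rose and 6 fell. With an estimated correlation 3 passed, HSC ageing, megakaryocyte and platelet, and lymphoid priming, each at an adjusted p of 0.0212. The other 18 lists did not pass. Their medians were 0.40 for mature neutrophils, -0.50 for MHC class I, 2.33 for B cells, 1.92 for T and NK cells, -1.17 for stromal cells, -0.95 for immediate early genes, 0.34 for heat shock, 0.35 for the unfolded protein response, 0.32 for glycolysis, -0.11 for ribosomal proteins, -0.31 for mitochondrially encoded genes, 0.49 for heme and iron and 0.26 for sex-linked genes. For 5 lists the median, the mean and the test differed in sign. They were dendritic (median -0.02, mean 0.81), erythroid (0.45, mean 0.06, tested down), NF-κB (-0.09, mean 0.23, tested down), p53 (-0.18, mean -0.13, tested up) and cholesterol (0.02, mean -0.01).

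**Figure D1:**
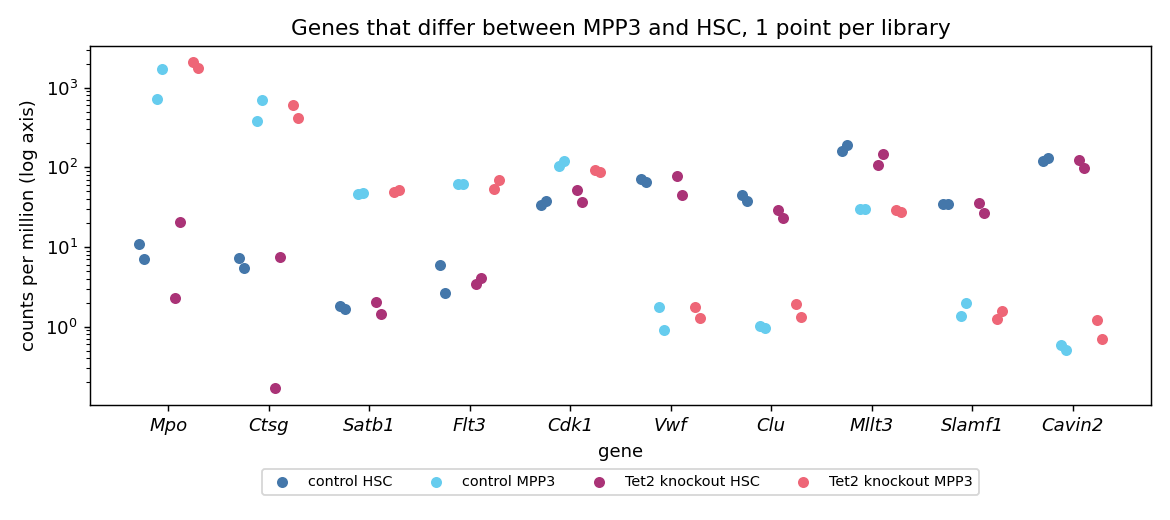
CPM on a log axis for genes that separate MPP3 from HSC, with 1 point per library. Mpo lies far higher in MPP3 than in HSC, and Vwf and Cavin2 far lower.

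In Tet2 knockout mice, MPP3 differed from HSC by similar programmes. Mpo went from 11.5 to 1913 CPM (log2 fold change 7.33, SE 1.00, adjusted p = 0.00254) and Cavin2 had a log2 fold change of -6.87 (SE 0.28, adjusted p = 1.91e-05). With edgeR 1541 genes rose and 1644 fell, 796 and 1275 of them at least 2-fold, and DESeq2 called 3853. Without knockout MPP3 1 or 2, edgeR called 1024 and 1690 genes. Of these 3185 genes, 2379 were also called in control mice in the same direction, 1066 up and 1313 down, against 138.5 and 178.5 expected if the calls were independent, and 1 was called in the opposite direction.

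HSC identity genes fell again in knockout MPP3 (23 of 30 down, none up, median -1.56, adjusted p = 4.23e-25, 0.104 with an estimated correlation), with Slamf1 at -4.46, Mllt3 at -2.16 and Tcf15 at -2.79. Ageing genes had 23 of 30 down, 2 up and a median of -2.95 (adjusted p = 3.91e-34), with Clu at -4.02 and Vwf at -5.33. Platelet genes had 15 of 19 down, none up and a median of -2.09 (adjusted p = 2.95e-26). Platelet factor 4, Pf4, went from 466 to 20.4 CPM (log2 fold change -4.51). Self-renewal regulators had 9 of 21 down, none up and a median of -0.52 (adjusted p = 2.85e-05, 0.418 estimated), with Prdm16 at -1.78 and Hoxb5 at -2.42, and a median of -0.84 without knockout MPP3 2. Quiescence genes had 6 of 18 down, 3 up and a median of -0.30 (adjusted p = 0.0245, 0.565 estimated), with Cdkn1c at -2.42 and Ndn at -3.46. Mitochondrially encoded genes had 3 of 13 down, none up and a median of -0.33 (adjusted p = 0.0269, 0.671 estimated), and interferon response genes had 7 of 37 down, 2 up and a median of -0.39 (adjusted p = 0.0245, 0.671 estimated). The quiescence call ended without knockout MPP3 1 (-0.19), with a median of -0.12 without knockout HSC 2. The mitochondrial call ended without knockout HSC 2 (-0.25) or knockout MPP3 1 (-0.38), and the interferon call without knockout MPP3 2 (-0.33). Adjusted over the list alone, 23 identity, 25 ageing, 16 platelet, 10 self-renewal, 6 quiescence, 3 mitochondrial and 8 interferon genes were lower, and 2 ageing, 1 self-renewal, 3 quiescence and 3 interferon genes were higher.

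Myeloid granule genes rose in knockout MPP3 (15 of 18 up, none down, median 2.71, adjusted p = 5.8e-21, 0.0833 estimated), with Ctsg at 6.92 (3092-fold without knockout HSC 2, counting interval 1058 to 14994, from 3 counts). Monocyte and macrophage genes had 13 of 16 up, none down and a median of 2.74 (4.18 without knockout HSC 2, or 3.77 at the bound, adjusted p = 1.39e-12, 0.124 estimated). Coagulation factor XIII, F13a1, had a log2 fold change of 7.23 (SE 0.76, adjusted p = 0.000883), Ly6c2, which encodes a Ly6C antigen of monocytes, one of 5.21 (SE 0.59, adjusted p = 0.00121), and Csf1r, the receptor of M-CSF, one of 4.95. Myeloid regulators had 10 of 20 up, none down and a median of 1.14 (adjusted p = 5.4e-06, 0.124 estimated), with Cebpa at 4.02, Irf8 at 3.49 and Spi1, which encodes PU.1, at 1.44. The calls of Csf1r (4.61) and Cebpa (3.87) ended without both libraries that held almost no female-marked cells, knockout HSC 1 and knockout MPP3 1. Basophil and mast genes had 8 of 12 up, 1 down and a median of 5.01, or 4.66 at the bound (adjusted p = 1.24e-11, 0.111 estimated). Cpa3 was at 4.49, and Mcpt8 was at least 791-fold higher. Eosinophil genes had 3 of 6 up and a median of 4.46, or 2.64 at the bound (adjusted p = 0.00373, 0.124 estimated), and 6.98 without knockout HSC 2, or 2.49 at the bound. Dendritic and MHC class II genes had 3 of 14 up, none down and a median of 0.45 (adjusted p = 0.023, 0.579 estimated). That call ended without knockout HSC 1 (0.45) or knockout MPP3 1 (0.27), and the median was 0.70 without knockout HSC 2, or 0.49 at the bound. Ccl9 was at 5.18 (SE 0.31, adjusted p = 8.4e-05). With p adjusted over the list alone, 15 granule, 15 monocyte, 11 regulator, 10 basophil, 4 eosinophil and 3 dendritic genes were higher and 1 basophil gene was lower.

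Lymphoid priming genes had 12 of 18 up, 1 down and a median of 3.61 in knockout mice (adjusted p = 1.54e-18), with Satb1 at 4.93, Flt3 at 3.999 and Dntt at 8.85 (at least 217-fold higher without knockout HSC 2). T and NK cell genes had 9 of 13 up, none down and a median of 5.31, or 4.72 at the bound (adjusted p = 2.85e-05, 0.479 estimated). The interleukin receptor chain Il2rb was at 7.29 (SE 1.47, adjusted p = 0.0123), the chemokine gene Ccl5 at 4.43 (SE 0.73, adjusted p = 0.00563) and Ms4a4b at 5.09. T and NK-like cells were more common in MPP3, and with mature clusters left out the median of the list was 2.47, Ccl5 was at 2.29, Ms4a4b at 3.01 and the Il2rb call ended (4.07). The Il2rb call also ended without knockout HSC 1 (262-fold, interval 72.5 to 2163), knockout HSC 2 (79.2-fold, interval 21.9 to 654), each with 2 counts left in HSC, or knockout MPP3 1 (5.61), and Ccl5 was at 2.94 without knockout MPP3 1. B cell genes had 1 of 12 up and a median of 2.32 (8.47 without knockout HSC 2, or 3.88 at the bound, adjusted p = 0.00206, 0.579 estimated). Homing receptors had 5 of 15 up, 3 down, a median of 0.06 and a mean of 0.62 (adjusted p = 0.00423, 0.214 estimated), and the median ran from -0.07 to 0.24 with single libraries left out. Adjusted over the list alone, 13 lymphoid, 9 T and NK and 5 homing genes were higher and 1 lymphoid and 4 homing genes lower.

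G2/M genes had 24 of 30 up, none down and a median of 1.17 in knockout mice (adjusted p = 2.57e-17, 0.323 estimated), and S-phase genes 25 of 30 up and a median of 0.96 (adjusted p = 5.48e-18, 0.226 estimated), with Birc5 at 1.41, Ube2c at 1.44 and the replication helicase gene Mcm5 at 1.23. The DNA methylation machinery had 3 of 15 up and a median of 0.26 (adjusted p = 0.023, 0.579 estimated), lost without knockout HSC 2 (0.26) or knockout MPP3 2 (0.17). Oxidative phosphorylation had 5 of 36 up and a median of 0.37 (adjusted p = 0.000457, 0.671 estimated), which was 0.16 without knockout MPP3 1. The unfolded protein response had 3 of 19 up, 1 down and a median of 0.56 (adjusted p = 0.0089, 0.579 estimated), lost without knockout HSC 1 (0.34) and 0.89 without knockout HSC 2, or 0.63 at the bound. Heme and iron genes had 1 of 14 up, the first enzyme of heme synthesis Alas1 at 1.53 (SE 0.36, adjusted p = 0.0221), and a median of 0.58 (adjusted p = 0.0263, 0.575 estimated). The list call ended without knockout HSC 1 (0.46) or knockout MPP3 1 (0.16), and the Alas1 call without knockout HSC 1 (1.21), knockout MPP3 1 (1.46) or knockout MPP3 2 (1.57). With p adjusted over the list alone, 26 G2/M, 29 S-phase, 4 methylation, 3 oxidative phosphorylation, 6 unfolded protein and 1 heme gene were higher.

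In knockout mice 23 lists passed, 16 up and 7 down. With an estimated correlation HSC ageing, megakaryocyte and platelet, and lymphoid priming passed, each at an adjusted p of 0.0233. The medians of lists that did not pass were 0.27 for mature neutrophils, -0.23 for MHC class I, -0.90 for stromal cells, 0.04 for NF-κB, -0.46 for immediate early genes, 0.36 for heat shock, 0.38 for glycolysis, 0.14 for cholesterol synthesis, 0.12 for ribosomal proteins and -0.12 for sex-linked genes. The erythroid list had a median of 0.18 and a mean of 0.30 but tested down, and the p53 list had a median of 0.12 and a mean of -0.02.

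In HSC, no gene passed the test between Tet2 knockout and control mice with edgeR. At an unadjusted p under 0.05 there were 761 genes, where 812 would come by chance, the smallest adjusted p was 0.811, and DESeq2 called 12 genes (4 up, 8 down). G2/M, DNA methylation and S-phase lists were higher in knockout HSC. HSC ageing, HSC identity, ribosomal protein and oxidative phosphorylation lists were lower. These medians, from -0.42 to 0.47, nearly vanished without knockout HSC 1 for G2/M, methylation, S-phase and identity. Of 35 lists, 11 passed camera (4 up, 7 down). None did with fry or an estimated correlation (adjusted p 0.880 for all 11).

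All 30 G2/M genes had positive log2 fold changes in knockout HSC, with a median of 0.47 (adjusted p = 8.98e-13 by camera). Polo-like kinase 1, Plk1 (chromosome 7, 122159439 to 122169873, plus strand), was at 0.73 (SE 0.25), Ccna2 at 0.69, Ccnb1 at 0.61 and Ube2c at 0.60, each with an adjusted p of 0.811. Without knockout HSC 1 the median was 0.01, and without knockout HSC 2 it was 0.82. S-phase genes had 28 of 30 positive and a median of 0.16 (adjusted p = 0.000927), with Dtl at 0.50 and Mcm2, a subunit of the replication helicase, at 0.32. That call ended without knockout HSC 1 (0.02) or control HSC 1 (0.05) and in male-marked cells alone (0.05), and the median was 0.28 and 0.29 without control HSC 2 and knockout HSC 2. The DNA methylation machinery had 13 of 15 positive and a median of 0.23 (adjusted p = 0.00162), with Tet3, a paralogue of Tet2, at 0.63 (SE 0.29), Ogt, a partner of TET proteins, at 0.59 (SE 0.19) and the glycosylase gene Tdg at 0.32. Its median was 0.02 without knockout HSC 1, which ended the call, and 0.43 without knockout HSC 2. Mitochondrially encoded genes had 12 of 13 positive and a median of 0.25 (adjusted p = 0.00253), with mt-Nd3 at 0.55. Their call ended without control HSC 1 (0.03) or knockout HSC 2 (0.07) and over all barcodes (0.16), and the median was 0.61 without control HSC 2. No member of any of these lists passed over all genes or adjusted over the list alone.

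HSC ageing genes had 27 of 30 members lower in knockout HSC and a median of -0.42 (adjusted p = 7.9e-08), a call that held without any single library. The chaperone gene Clu (chromosome 14, 65968483 to 65981547, plus strand) was at -0.65 (SE 0.21), Jam2 at -0.59 (SE 0.19), the netrin receptor family gene Neo1 (chromosome 9, 58874687 to 59036441, minus strand) at -0.91 (SE 0.30), and Gpr183, an oxysterol receptor that guides lymphocyte migration (chromosome 14, 121952551 to 121965195, minus strand), at -1.44 (SE 0.44), with 25.5 CPM in control and 9.26 CPM in knockout. HSC identity genes had 25 of 30 lower and a median of -0.20 (adjusted p = 0.00371), with Mllt3 at -0.48, Tcf15 at -0.50 and the interferon-inducible membrane gene Ifitm1 at -0.64 (SE 0.26, 1284 against 826 CPM). That call ended without knockout HSC 1 (-0.01) or control HSC 2 (-0.03) and in male-marked cells (-0.09), and the median was -0.31 and -0.40 without control HSC 1 and knockout HSC 2. All 76 ribosomal protein genes were lower, with a median of -0.37 (adjusted p = 9.55e-15), among them Rps23 at -0.54 (SE 0.20, 5301 against 3648 CPM), Rps18 at -0.52 and Rpl26 at -0.51. The median was -0.18 without knockout HSC 1 and -0.60 without knockout HSC 2. Signs of RNA quality moved too: the median mitochondrial share was 3.75% and 4.05% in knockout and 2.46% and 3.65% in control HSC, and Gm42418 and Lars2, linked to ribosomal RNA and chosen after their values were seen, were at -1.04 and -0.97. Oxidative phosphorylation genes had 34 of 36 lower and a median of -0.32 (adjusted p = 1.38e-07; -0.13 without control HSC 1), with the complex III genes Uqcrh at -0.48 and Uqcrb at -0.47.

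Monocyte and macrophage genes had 14 of 16 lower in knockout HSC and a median of -0.72 (adjusted p = 0.00253). Ly6c2 (chromosome 15, 75108158 to 75111970, minus strand) was at -2.47 (SE 0.56), with 7.38 and 20.8 CPM in control libraries against 2.52 and 2.54 in knockout libraries, and passed adjusted over the list alone. The chemokine receptor gene Ccr2 was at -2.19. The monocyte call ended without control HSC 1 (0.30) or knockout HSC 2 (-1.28, or -1.15 at the bound) and with mature clusters left out (-0.27), and the median was -1.38 without control HSC 2. B cell genes had 8 of 12 lower and a median of -0.57 (adjusted p = 0.00893). Their median was 0.03 without knockout HSC 1, -0.32 without control HSC 1, -0.46 without mature clusters and -0.11 in cells of at least 5000 UMIs, each of which ended the call, and it was -0.99 without control HSC 2 and -6.17, or -1.18 at the bound, without knockout HSC 2. Immediate early genes had 22 of 24 lower and a median of -0.34 (adjusted p = 0.024). Their sign turned without control HSC 1 (0.27) or knockout HSC 1 (0.13), the call ended with clusters 2, 7, 8 and 13 left out (-0.16) or the replicate block (-0.33), and the median was -0.66 and -0.97 without control HSC 2 and knockout HSC 2.

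The other 24 lists did not pass in HSC. Medians were 0.08 for granule proteases, -0.15 for myeloid regulators, -0.25 for dendritic, -0.19 for MHC class I, -0.04 for platelet, 0.42 for erythroid, 0.03 for basophil, -0.66 for eosinophil, -0.13 for lymphoid priming, -1.18 for T and NK, 0.14 for heat shock, -0.02 for unfolded protein, -0.11 for quiescence, -0.05 for self-renewal, -0.04 for glycolysis, 0.03 for cholesterol, 0.10 for heme, -0.08 for homing and 1.18 for sex-linked genes. The self-renewal list tested up against its median. Mature neutrophil genes had a median of 0.70 but a mean of -0.33, with the calprotectin gene S100a8 at 1.28 from 545 CPM in knockout HSC 1 and 120 CPM in knockout HSC 2. Median and mean also differed in sign or from the test for stromal (-0.33, mean -0.09, tested up), interferon (0.06, mean -0.09), NF-κB (0.07, mean -0.01) and p53 genes (0.00, mean -0.05, tested up).

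In MPP3, again no gene passed between the genotypes with edgeR, with 528 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.258, and 20 genes called by DESeq2 (6 up, 14 down). With the replicate block Il2rb (adjusted p = 0.0199) and others passed. T and NK cell, basophil, interferon, NF-κB and platelet genes were higher in knockout MPP3 as lists, and ribosomal protein and oxidative phosphorylation genes were slightly lower. Of 35 lists, 13 passed camera (11 up, 2 down). None passed with an estimated correlation, at adjusted p between 0.844 and 0.852, nor with fry. Without the block no member passed over all genes or adjusted over the list alone, and genes named below had an adjusted p of 1 unless given.

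T and NK cell genes had 12 of 13 members higher in knockout MPP3 and a median of 2.24 (adjusted p = 1.46e-09). They include the natural killer receptor genes Klrb1c at 2.35 (SE 0.73) and Ncr1 at 2.95 (SE 1.00), Il2rb at 2.74, granzyme B, Gzmb, at 1.34, and Ccl5 at 1.82 (SE 0.63), which had 104 and 23.04 CPM in knockout libraries against 22.9 and 12.9 in control libraries. T and NK-like cells made up 6.37% and 1.13% of knockout MPP3 and 1.53% and 0.373% of control MPP3, and with mature clusters left out the call ended at a median of 0.60. The median was 0.61 without knockout MPP3 1, 4.21 without control MPP3 1, and 1.45 without control MPP3 2, which ended the call. Basophil and mast genes had 11 of 12 higher and a median of 0.40 (adjusted p = 0.000395), with the IgE receptor gene Fcer1a at 1.00 and the steroidogenic enzyme gene Cyp11a1 at 0.94. Basophil-like cells made up 4.65% and 1.47% of knockout and 1.04% and 2.67% of control MPP3. The basophil call ended without knockout MPP3 1 (0.09) and with clusters 2, 7, 8 and 13 left out (0.29), and the median was 0.78 and 0.93 without control MPP3 2 and knockout MPP3 2.

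Interferon response genes had 29 of 37 higher and a median of 0.23 (adjusted p = 0.000244), with Slfn2 at 0.97 and the GTPase genes Igtp at 0.81 and Iigp1 at 0.85. Iigp1 had 78.0 and 31.4 CPM in knockout and 30.1 and 30.4 CPM in control libraries. That call ended without knockout MPP3 1 (0.09) or control MPP3 1 (0.13), and the median was 0.37 without knockout MPP3 2. NF-κB genes had 17 of 24 higher and a median of 0.25 (adjusted p = 0.00624), with Nfkb2 at 0.53 and Traf1 at 0.76, and the call ended without control MPP3 2 (0.13) or knockout MPP3 2 (0.18) and in male-marked cells (0.18). Without control MPP3 1 the median was 0.54. Myeloid regulators had 12 of 20 higher and a median of 0.05 (adjusted p = 0.0405), with Id2, an inhibitor of helix-loop-helix factors, at 1.20 (SE 0.33) and Irf8 at 0.64 (SE 0.18). The regulator call ended without control MPP3 1 (-0.01) or knockout MPP3 2 (-0.18), and the median was 0.39 and 0.20 without control MPP3 2 and knockout MPP3 1. Monocyte genes had 11 of 16 higher and a median of 0.36 (adjusted p = 0.0405), with Ccr2 at 1.04 and F13a1 at 0.96. Their call ended without control MPP3 2 (0.16), knockout MPP3 1 (0.10) or either knockout HSC library (both 0.36), the median was 0.69 and 0.56 without control MPP3 1 and knockout MPP3 2, and the sign turned with clusters 2, 7, 8 and 13 left out (-0.12).

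Platelet genes had 13 of 19 higher in knockout MPP3 and a median of 0.17 (adjusted p = 0.0105), with Clu at 0.71, Cavin2 at 0.78 and the integrin gene Itgb3 at 0.74. The platelet call ended without control MPP3 1 (0.07) or knockout MPP3 2 (0.18), and the median was 0.29 without control MPP3 2. Erythroid genes had 15 of 20 higher and a median of 0.49 (adjusted p = 0.0456), with the transcription factor genes Gata1 at 0.87 and Gfi1b at 0.68. Erythroid-like cells made up 5.70% and 0.919% of knockout and 3.99% and 1.07% of control MPP3. The erythroid sign turned without knockout MPP3 1 (-0.69), and the call ended without control MPP3 2 (0.21), without any HSC library (0.50) and with RLE size factors (0.50) or the replicate block (0.36). The median was 1.00 and 1.06 without control MPP3 1 and knockout MPP3 2. Heme and iron genes had 12 of 14 higher and a median of 0.18 (adjusted p = 0.0405), with coproporphyrinogen oxidase, Cpox, at 0.63. Their sign turned without knockout MPP3 1 (-0.11) and the call ended without control MPP3 2 (0.04), with 0.48 and 0.49 without control MPP3 1 and knockout MPP3 2. Glycolysis genes had 14 of 15 higher and a median of 0.20 (adjusted p = 0.0154), lost without control MPP3 2 (0.25) or knockout MPP3 1 (0.14) and 0.13 without control MPP3 1. Cholesterol synthesis had 16 of 19 higher and a median of 0.11 (adjusted p = 0.0405), lost without control MPP3 2 (0.10), knockout MPP3 1 (0.14) or knockout MPP3 2 (0.21) and with the replicate block (0.11).

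Ribosomal protein genes had 59 of 76 lower in knockout MPP3 and a median of -0.09 (adjusted p = 0.028), with Rps23 and Rps18 both at -0.54. The sign turned without control MPP3 1 (0.04), the call ended without knockout MPP3 2 (-0.01) and with the replicate block (-0.09), and the median was -0.20 and -0.17 without control MPP3 2 and knockout MPP3 1. Oxidative phosphorylation had 28 of 36 lower and a median of -0.11 (adjusted p = 0.0405), with Cox7b at -0.39. Its median was 0.02 without control MPP3 1 and 0.07 without knockout MPP3 2 and -0.12 with the replicate block, each of which ended the call, and -0.19 and -0.27 without control MPP3 2 and knockout MPP3 1.

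The other 22 lists did not pass in MPP3. Medians were 0.06 for HSC identity, 0.15 for HSC ageing, 0.14 for granule proteases, 0.15 for dendritic, 0.07 for MHC class I (Tapbp at 0.36, Nlrc5 at 0.50), 0.07 for lymphoid priming, 0.15 for stromal, 0.09 for immediate early, 0.14 for heat shock, 0.12 for unfolded protein, -0.07 for G2/M, -0.01 for S phase, -0.11 for quiescence (Klf9 at 0.40), 0.07 for p53, 0.08 for methylation, -0.10 for self-renewal (Hmga2 at 0.96), 0.21 for mitochondrially encoded, -0.03 for homing and 0.37 for sex-linked genes. Mature neutrophil genes had a median of 0.38 but a mean of -0.19, B cell genes a median of -0.21 and a mean of -0.12 but tested up, and eosinophil genes a median of -0.16 but tested up.

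**Figure D2:**
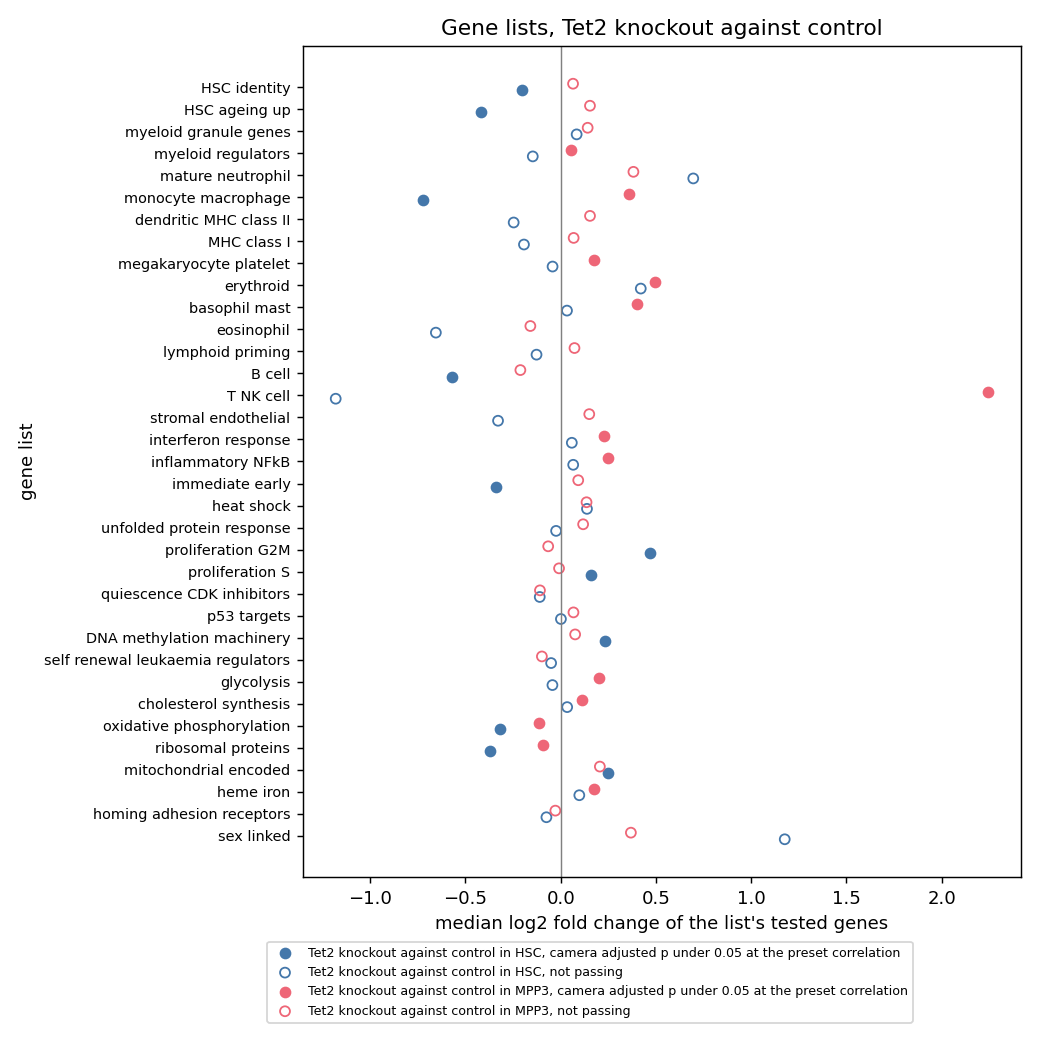
Median log2 fold change of each gene list between Tet2 knockout and control in HSC and in MPP3. Filled points passed camera at the preset correlation, and none passed with an estimated correlation. In HSC the G2/M list lies at 0.47, and in MPP3 the T and NK list at 2.24.

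The genotype effects in HSC and MPP3 were weakly related. Across the 16239 genes the Pearson correlation of the log2 fold changes was 0.164 and the Spearman correlation 0.310, and at a mean of at least 20 CPM (6073 genes) they were 0.171 and 0.473. Without control MPP3 1 the values over all genes were -0.01 and 0.02. At an unadjusted p under 0.05 in both populations there were 73 genes, and 69 of them had the same sign. Independent tests would give 24.7, but the populations were not independent, since the difference between replicates was correlated between HSC and MPP3 (0.580 in control, 0.306 in knockout), so the overlap does not show a shared effect of Tet2.

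Whether the loss of Tet2 acted differently in the populations was tested by the interaction. No gene passed with edgeR (255 at an unadjusted p under 0.05, smallest adjusted p of 1), and DESeq2 called 3 (1 up, 2 down). These were chosen after their values were seen: Hist1h2ab at -2.46, Hist2h2ac at -1.95, both replication-dependent histone genes, and the antiprotease gene Slpi at 2.15. Clu was at 1.36 (SE 0.31) and Ly6c2 at 3.12 (SE 0.73), and passed adjusted over the platelet and monocyte lists alone, Clu not over the HSC ageing list. Other genes with large differences were Gpr183 at 2.45 (SE 0.63), Klrb1c at 3.77 (SE 1.02), Cd7 at 4.38, Id2 at 1.65, Cavin2 at 0.95, Hk2 at 0.66, Cdk1 at -0.60, Ccnb1 at -0.66 and Ube2c at -0.62. Tet2 was at -0.32. Of 35 lists, 18 passed camera, and none did with an estimated correlation. They are described with their values in the closing section. The 17 others had medians of 0.22 for erythroid, 0.11 for basophil, 0.74 for eosinophil, 0.21 for stromal, 0.13 for NF-κB, 0.00 for heat shock, 0.13 for quiescence, 0.01 for p53, -0.20 for methylation, -0.09 for self-renewal, 0.13 for cholesterol, -0.02 for mitochondrially encoded, 0.10 for heme and -0.57 for sex-linked genes. Granule proteases were at 0.15 (mean -0.00), mature neutrophils at -0.40 (mean 0.14) and homing receptors at -0.03 (mean 0.01).

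Cells were named by class from markers. In the HSC sort, HSC-like cells made up 46.6% and 73.3% of control and 48.0% and 48.7% of knockout libraries. Control HSC 1 stood at 59.6%, 58.0% and 61.4% at resolution 0.5, at resolution 2 and without cell cycle genes, and the 1327 shallow cells of knockout HSC 2 stayed unnamed, with HSC-like as their closest class, which lowers its share. Megakaryocyte-like cells, rich in platelet genes, made up 20.6% and 14.0% of control and 24.9% and 7.90% of knockout libraries. In the MPP3 sort, HSC-like cells were 1.49% and 3.52% of control and 0.842% and 1.27% of knockout cells, and myeloid progenitor-like cells 2.21% and 6.45% of control and 6.91% and 3.65% of knockout cells. Knockout HSC 1 held 0 of 1178 myeloid progenitor-like cells, with an upper limit of 0.313%. Most MPP3 cells stayed unnamed (85.5% and 84.4% of control, 72.3% and 89.2% of knockout), as few of their clusters met the marker rule. Basophil or mast-like cells were 0.328% and 0.610% of control HSC against 5.603% and 0.671% of knockout HSC. Erythroid-like cells were 0.938% and 0.888% of control HSC against 4.92% and 1.21% of knockout HSC. The basophil name of the cells in knockout HSC is not settled. No UMI of Mcpt8, a marker of the class, was found in either library, and both at resolution 0.5 and without cell cycle genes knockout HSC 1 held 0 of 1178 basophil or mast-like cells, with 10.2% and 10.3% erythroid-like cells.

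No class share passed between the genotypes or for the interaction with edgeR. The smallest adjusted p was 0.303, for basophil or mast-like cells in HSC at a log2 fold change of 2.72. At resolution 0.5 that fold was -0.88, and without knockout HSC 1 it was 0.52. T or NK-like cells in MPP3 were at 1.97 (adjusted p = 0.878). Between the populations, control MPP3 held fewer HSC-like cells (log2 fold change -4.58, adjusted p = 0.00321) and megakaryocyte-like cells (-5.52, adjusted p = 0.00175) and more myeloid progenitor-like cells (5.78, adjusted p = 0.00175). The call of HSC-like cells ended without control MPP3 1 (-4.09). Knockout MPP3 held fewer HSC-like (-5.51) and megakaryocyte-like cells (-5.42) and more myeloid progenitor-like (6.57) and T or NK-like cells (6.31), each at an adjusted p of 0.000646, and more macrophage-like cells (3.49, adjusted p = 0.0237). The myeloid, T or NK and macrophage folds rest on 3, 2 and 6 cells in knockout HSC. Without knockout HSC 2 the T or NK call ended, with 1 cell left, and no fold is given for myeloid and macrophage cells, of which knockout HSC 1 held 0. The macrophage call ended without knockout HSC 1 (2.86) or knockout MPP3 1 (3.30).

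**Figure D3:**
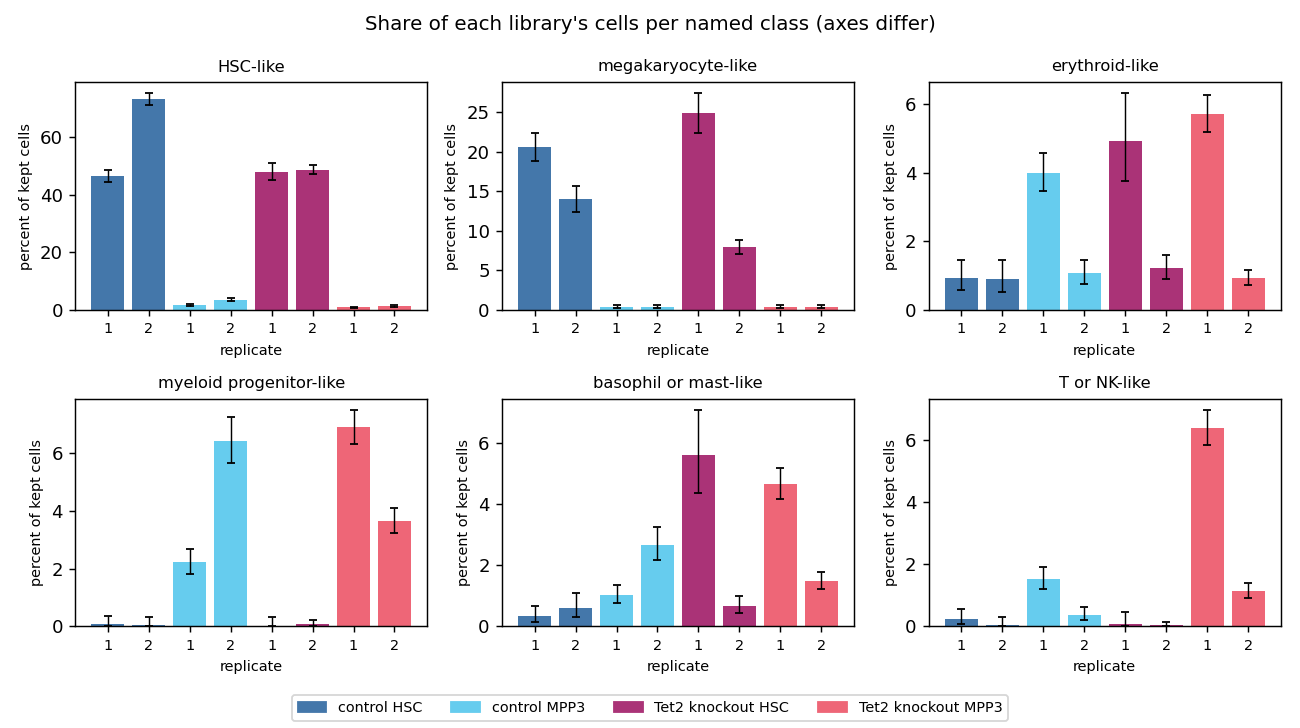
Percent of a library's kept cells in each named class, with 1 bar per library and 95% exact binomial intervals. HSC-like and megakaryocyte-like cells fill most of the HSC sort.

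Cells with G2/M transcripts were more common in MPP3 than in HSC. At 4000 UMIs per cell, 10.6% and 10.8% of control HSC had at least 3 UMIs over the G2/M list, against 36.2% and 46.0% of control MPP3. Knockout HSC had 22.9% (95% interval 20.5% to 25.4%) and 12.5% (11.3% to 13.8%), and knockout MPP3 42.2% and 35.7%. Within the HSC sort, clustered without cell cycle genes, 2.53% and 2.67% of HSC-like cells of knockout libraries and 1.70% and 2.12% of control libraries had such transcripts, against 45.3%, 40.1%, 32.2% and 43.2% of megakaryocyte-like cells at the same depth of 4000 UMIs. Thinning left out 1220 cells of knockout HSC 2 and 46 to 381 of each other library.

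**Figure D4:**
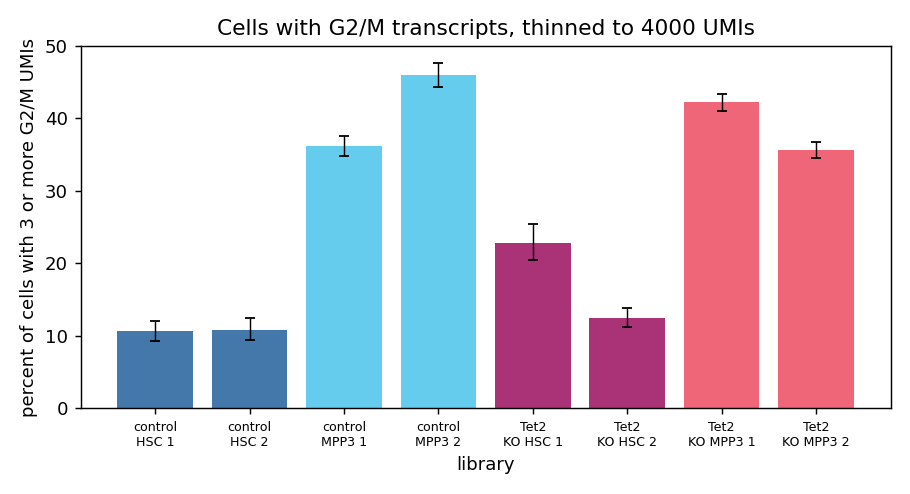
Percent of cells with at least 3 UMIs over the G2/M list after thinning to 4000 UMIs, with 1 bar per library and 95% exact binomial intervals. Knockout HSC 1 lies at 22.9%, above the other HSC libraries at 10.6% to 12.5%.

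Within classes, few genes passed between the genotypes with edgeR, and their number depended on the model. With the replicate block 114, 37 and 80 genes passed in HSC-like, megakaryocyte-like and myeloid progenitor-like cells in place of 2, 5 and 4, and at resolution 0.5 none passed in megakaryocyte-like cells. In HSC-like cells of the HSC sort, 2 of 13289 genes fell (687 at an unadjusted p under 0.05, DESeq2 12). Gpr183 was at -1.48 (SE 0.22, adjusted p = 0.0250), with 52.8 and 40.4 CPM in control and 16.3 and 17.1 CPM in knockout cells, and the long non-coding RNA Gm26885 at -3.47 (SE 0.48, adjusted p = 0.0183). Without knockout HSC 1 both calls ended, at -1.44 and -3.38. They ended too without knockout HSC 2, at -1.52 and -3.81, and the Gpr183 call without control HSC 1, at -1.28. In megakaryocyte-like cells 5 of 11808 genes passed. Eif2s3y (1.63, on chromosome Y), AA465934 (1.22) and Gm10457 (3.26) rose, and 1500009L16Rik (-1.25) and the Notch ligand family gene Dlk1 (-3.29) fell, while DESeq2 called 3. AA465934 was also higher in female-marked than in male-marked cells (30.4 against 3.81 CPM). Without control HSC 1 the calls of Eif2s3y (1.52), AA465934 (1.32) and 1500009L16Rik (-1.33) ended, without control HSC 2 those of AA465934 (1.15), 1500009L16Rik (-1.18) and Gm10457 (2.77), and without knockout HSC 1 that of Gm10457 (2.61). Dlk1 had 14.95 and 1.503 CPM in control and 0.934 and 0.829 CPM in knockout libraries, and its call ended at resolution 0.5 (-2.97) and with DESeq2 (-3.24). In myeloid progenitor-like cells of the MPP3 sort, 4 of 11279 genes passed and DESeq2 called 20. All 4 are replication-dependent histone genes that fell: Hist1h2ab (-2.02, SE 0.14, adjusted p = 0.0242), Hist1h4d (-1.80), Hist1h3c (-1.73) and Hist1h3e (-1.48). The names in this paragraph were chosen after their values were seen.

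**Figure D5:**
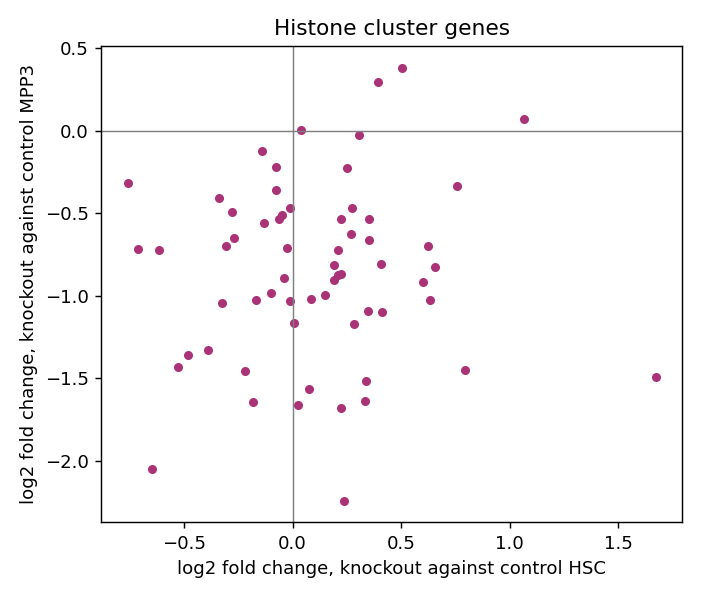
Log2 fold change of the 62 histone genes between Tet2 knockout and control, in HSC (across) and MPP3 (upwards), 1 point per gene. In MPP3 58 genes lie below 0. The set was chosen after the values were seen.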

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

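The weighing of G2/M genes below used tests on single libraries and on class makeup that were chosen after the result was seen, and the test on donor sex was written down before its value was known. In 18 of 35 gene lists the effect of Tet2 loss differed between MPP3 and HSC by camera on the interaction. All values are the median log2 difference, MPP3 effect minus HSC effect. None of the 18 passed with an estimated correlation, where the adjusted p lay between 0.504 and 0.754, and with control HSC 1 left out 11 lists passed.

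T and NK cell genes differed by 3.39 (adjusted p = 2.23e-10, 0.504 with an estimated correlation), with all 13 members positive. Their value was 0.71 without control HSC 1 (0.97 with genes at 0 set to their bound), 2.20 without control MPP3 2 and 1.94 without knockout MPP3 1, and the call ended with mature clusters left out (0.23). HSC ageing genes differed by 0.42 (adjusted p = 2.23e-10, 0.504 estimated), with 27 of 30 positive, and by 0.28 to 0.71 with single libraries left out. Monocyte and macrophage genes differed by 0.91 (adjusted p = 1.09e-06, 0.504 estimated), lost without control HSC 1 (-0.12), and by 0.46 to 1.76 (1.63 at the bound) without other single libraries. Megakaryocyte and platelet genes differed by 0.21 (adjusted p = 0.000606, 0.504 estimated), lost without knockout HSC 2 (0.21), by 0.50 without knockout HSC 1, and by 0.13, 0.13 and 0.14 without control HSC 1, control MPP3 1 and knockout MPP3 2. Lymphoid priming genes differed by 0.18 (adjusted p = 0.005, 0.504 estimated), lost without control HSC 1 (0.19) or control MPP3 2 (0.21, or 0.16 at the bound), and by 0.09 without knockout MPP3 2. B cell genes differed by 0.29 (adjusted p = 0.0022, 0.655 estimated), lost without control HSC 1 (0.11), control MPP3 2 (-0.26), knockout HSC 1 (-0.16) or knockout MPP3 1 (0.19), and by 1.04, 2.20 and 6.06 (1.55 at the bound) without control HSC 2, control MPP3 1 and knockout HSC 2.

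Interferon genes differed by 0.16 (adjusted p = 0.000501, 0.655 estimated), lost without control HSC 2 (-0.01), control MPP3 1 (0.11) or knockout MPP3 1 (0.07), and by 0.37, 0.33, 0.34 and 0.27 without control HSC 1, control MPP3 2, knockout HSC 2 and knockout MPP3 2. HSC identity genes differed by 0.30 (adjusted p = 0.00465, 0.655 estimated), lost without control HSC 2 (0.11), control MPP3 1 (0.18), knockout HSC 1 (0.11) or knockout MPP3 2 (-0.09), and by 0.48 without knockout HSC 2. Myeloid regulators differed by 0.31 (adjusted p = 0.022, 0.655 estimated), lost without control HSC 1 (-0.03), control MPP3 1 (0.28), knockout HSC 1 (-0.01) or knockout MPP3 2 (-0.04), and by 0.76 without knockout HSC 2. Dendritic genes differed by 0.57 (adjusted p = 0.0103, 0.655 estimated), lost without control HSC 1 (0.01, or 0.22 at the bound), control MPP3 2 (0.19) or knockout MPP3 1 (0.21), and by 1.04 without control MPP3 1. MHC class I genes differed by 0.20 (adjusted p = 0.0201, 0.655 estimated), lost without control HSC 2 (0.18), control MPP3 1 (0.23), knockout HSC 1 (0.06) or knockout MPP3 1 (0.15), and by 0.33 without knockout HSC 2. Immediate early genes differed by 0.46 (adjusted p = 0.00233, 0.698 estimated), lost without control HSC 1 (-0.06), control MPP3 2 (0.06), knockout HSC 1 (0.01) or knockout MPP3 2 (-0.18), and by 0.84, 0.94, 1.17 and 0.83 without control HSC 2, control MPP3 1, knockout HSC 2 and knockout MPP3 1. The unfolded protein response differed by 0.19 (adjusted p = 0.0259, 0.674 estimated), lost without control HSC 2 (0.03), control MPP3 1 (0.01), knockout HSC 1 (0.00) or knockout MPP3 2 (0.06), and by 0.34, 0.32 and 0.41 without control HSC 1, control MPP3 2 and knockout HSC 2.

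Glycolysis genes differed by 0.21 (adjusted p = 0.00509, 0.655 estimated), lost without control HSC 2 (0.16) or knockout HSC 1 (0.02), and by 0.45 and 0.06 without knockout HSC 2 and knockout MPP3 1. Oxidative phosphorylation differed by 0.20 (adjusted p = 0.00391, 0.754 estimated), lost without control HSC 1 (0.06), control MPP3 2 (0.08) or knockout MPP3 1 (-0.02), and by 0.11 and 0.32 without knockout HSC 1 and knockout MPP3 2. Ribosomal proteins differed by 0.26 (adjusted p = 7.74e-07, 0.674 estimated), lost without control MPP3 2 (0.14) or knockout HSC 1 (0.09), and by 0.53 and 0.16 without knockout HSC 2 and knockout MPP3 1. S-phase genes differed by -0.16 (adjusted p = 0.000507, 0.674 estimated), lost without control HSC 1 (-0.09), control MPP3 2 (-0.11) or knockout HSC 1 (-0.00), and by -0.29, -0.26 and -0.26 without control HSC 2, control MPP3 1 and knockout HSC 2. G2/M genes differed by -0.53 (adjusted p = 1.29e-14, 0.655 estimated), with all 30 negative, the call ended without knockout HSC 1 (-0.03), and the value was -0.84 without knockout HSC 2.

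G2/M genes rose in knockout HSC, with a median of 0.47. In male-marked cells alone the median was 0.43, above 50% of 0.47, which argues against donor sex as the cause. Male-marked minus female-marked cells of a library differed by a mean of 0.21 (SD 0.24) over 6 libraries. Without knockout HSC 1 the median was 0.0123, so that library may carry most of the list's difference. Knockout HSC 2 had 12.5% G2/M cells against 10.6% and 10.8% in control at 3 or more UMIs, with overlapping intervals. At 2 or more it had 21.3% against 15.6% and 16.8%. Thinning left out 1220 of its cells, against 203 and 104 in control, so its rise is not settled. At the shares of G2/M cells that control libraries had within each class, the class makeup of knockout HSC 1 gave 18.7% against 22.9% observed and 10.7% in control, or 65.4% of the excess, while that of knockout HSC 2 gave 9.31% against 12.5% observed. The test does not decide, as the classes, formed without the listed cell cycle genes, differ widely in cycling. In control HSC 1.91% of HSC-like cells had G2/M transcripts against 36.5% of megakaryocyte-like and 45.3% of erythroid-like cells. Whether class depends on cycling was not tested. Class makeup and a change of cycling thus cannot be told apart. An earlier test, the list median in HSC-like cells (0.51, 24 of 29 positive), had the same limit and was replaced once seen. In megakaryocyte-like cells the median was -0.25 (8 of 30). An effect of Tet2 on cycling stays open.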

How the results depend on the processing

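Alternatives with male-marked cells alone, cells of at least 5000 UMIs, clusters 2, 7, 8 and 13 left out, the highest 6% of doublet scores left out, cells marked by both sexes left out, and both all-male libraries left out were chosen after seeing the data, as were all barcodes and mature clusters left out for lists, and DESeq2 within classes. All the other settings were fixed beforehand. Because Scrublet was set aside, the setting for doublets was run in reverse, as the 20 marked cells left out. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Over all alternatives, values of single genes kept direction and side of the threshold in 3948 cases, lost a call in 18, gained one in 4 and reversed in 10. Lists did so in 1162 cases, lost the call in 291 and reversed in 21. Class shares did so in 187, lost 4 and reversed 4, and genes within a class kept 55 and lost 21. Leading counts and values stayed within their limit in 295 cases, moved in 70 and reversed in 1. Scaling by RLE in place of TMM moved the median of all genes by at most 0.0168 and reversed no named gene or passing list. It turned 2 medians near 0, those of S-phase genes in MPP3 (-0.00872 to 0.000372) and p53 genes in HSC (0.00115 to -0.00572). Except where a setting tests fewer genes or libraries by construction, the cause was not tested. Simulations found 19.4% and 37.3% of 2-fold genotype changes in HSC and MPP3.

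For genotype in HSC, where edgeR called 0 genes, DESeq2 called 12, edgeR without a low-count filter 2, and the 4 libraries alone 1. No gene was called in HSC with any single library left out. For genotype in MPP3, again with 0 genes, DESeq2 called 20, no filter 19, the replicate block 5, and single libraries left out between 0 and 1. For MPP3 against HSC in control, with 3223 genes, a 1.5-fold minimum left 1484 and single libraries left out gave 1318 to 3780. In knockout, with 3185, the 1.5-fold minimum left 1318, both all-male libraries left out 1074, and single libraries left out 1024 to 2863. For the interaction, with 0 genes, DESeq2, no filter and the animal block each called 3. With the replicate block the populations differed by 4117 and 4096 genes, and with the animal block by 4740 and 4665.

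With an estimated correlation the passing lists went from 11, 13, 17, 23 and 18 to 0 for genotype in HSC, 0 for genotype in MPP3, 3 for the populations in control, 3 in knockout and 0 for the interaction. Fry called 0, 0, 12, 13 and 0 lists in that order, and its mixed test 0, 0, 26, 30 and 0. With both all-male libraries left out the interaction had 11 lists, and with single libraries left out 11 to 21.

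With both all-male libraries left out (knockout HSC 1 and knockout MPP3 1), reversed or near-zero values were -0.18 for S100a8 in HSC, -0.27 for Gata1 and -0.0261 for Cpox in MPP3, 0.13 for immediate early and 0.0189 for S-phase genes in HSC, -0.69 for erythroid and -0.11 for heme genes in MPP3, and -0.48 for B cell, -0.0574 for oxidative phosphorylation and 0.00902 for ribosomal genes in the interaction. With clusters 2, 7, 8 and 13 left out, monocyte genes in MPP3 were at -0.12 and erythroid genes at 0.000421. Tet2 in knockout MPP3 against HSC (0.09) was at -0.13 with 1000 cells per library and -0.0100 in male-marked cells.

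Single libraries left out gave these ranges where the tested direction turned. In HSC, Ccr2 ran from -3.04 to 0.78, S100a8 from -0.18 to 1.99, immediate early genes from -0.97 to 0.27, and S-phase genes from 0.0198 to 0.29, with the test reversed at the lower end. In MPP3, Gata1 ran from -0.27 to 1.51, Cpox from -0.0264 to 1.10, erythroid genes from -0.69 to 1.06, oxidative phosphorylation from -0.27 to 0.0716, ribosomal proteins from -0.20 to 0.0400, and heme genes from -0.11 to 0.49. For Tet2 between the knockout populations the range was -0.0480 to 0.19. In the interaction, immediate early genes ran from -0.18 to 1.17 and oxidative phosphorylation from -0.0181 to 0.32. Medians alone crossed 0, with the tested direction kept, for monocyte genes (0.30) and B cell genes (0.0279) in HSC, myeloid regulators in MPP3 (-0.18), homing genes in control (-0.0466) and knockout (-0.0672), and HSC identity (-0.0935), regulators (-0.0370), monocyte (-0.12), B cell (-0.26) and interferon genes (-0.00579) in the interaction. The correlation of the genotype effects ran from -0.0134 to 0.203 (Pearson) and from 0.0200 to 0.387 (Spearman), lowest without control MPP3 1. The log2 fold change of the HSC-like share in HSC (-0.31) ran from -0.60 to 0.0533, and that of the myeloid progenitor-like share in MPP3 (0.29) from -0.29 to 1.25.

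Leaving cell cycle and immediate early genes out of the clustering raised the classes passing between the control populations from 3 to 5, and at resolution 0.5 the basophil share in HSC was at -0.88 in place of 2.72. G2/M shares, as means of 2 libraries, were 10.7% in control HSC, 41.1% in control MPP3, 17.7% in knockout HSC and 39.0% in knockout MPP3. Without thinning they were 28.4%, 71.8%, 38.8% and 65.7%, and at a minimum of 2 UMIs 16.2%, 51.9%, 26.3% and 50.4%. At a minimum of 5 UMIs they were 7.61%, 31.7%, 13.2% and 29.97%. Over all barcodes Tet2 was at 15.02 CPM in control HSC and 23.6 CPM in knockout HSC.

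Within HSC-like cells (2 genes) the replicate block called 114, DESeq2 12 and single libraries left out 0 to 68. Within megakaryocyte-like cells (5) the block called 37, resolution 0.5 called 0, DESeq2 3, and single libraries left out 8 to 230. Within myeloid progenitor-like cells (4) the block called 80, DESeq2 20, and single libraries left out 7 to 38.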

Other observations

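All tests on histone genes and the test of chromosome 18 were chosen after the result was seen, as was the limit to autosomal genes in the test of other assignments of the sex marks, which had been written down with X-linked genes counted. Replication-dependent histone genes, which package newly made DNA and are transcribed in S phase, were lower in knockout MPP3. Of 62 such genes tested, 58 had negative log2 fold changes between knockout and control MPP3, with a median of -0.82 and 26 at an unadjusted p under 0.05. Hist1h4d had 41.3 and 40.6 CPM in knockout against 190 and 149 CPM in control libraries. The medians were -0.51 to -0.91 without single MPP3 libraries. The weakest was without control MPP3 1, which gave 567 of the 797 cells of cluster 6, a cluster led by these genes (609 of 647 when clustered without cell cycle genes), and 52 of 62 genes were then lower. In HSC, 36 of 62 were positive, and between the populations the median was 1.12 in control and 0.17 in knockout mice. Camera on these 62 genes in MPP3 gave p = 1.54e-48 at the preset correlation and p = 0.00942 with an estimated correlation of 0.244, on genes grouped after their values were seen. Some histone genes are near-identical copies, so their counts may be shared between copies, a point that the medians of -0.82 over all and -0.857 within myeloid progenitor-like cells do not settle.

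The S-phase list (median -0.00872 in MPP3) argues against fewer cells in S phase as the cause. Class makeup is argued against only within myeloid progenitor-like cells (57 of 59 histone genes lower, median -0.857). It stays open for unnamed cells, most of MPP3. Most histone transcripts lack poly-A tails, and transcripts linked to ribosomal RNA were lower in knockout libraries of both populations (Gm42418 at -1.04 in HSC and -1.50 in MPP3, AY036118 at -2.16 and -3.12, Lars2 at -0.97 and -1.50), so a lower capture of untailed RNA was tested. It would lower histone genes in HSC as well, where their median was 0.115. This cannot decide, as more G2/M cells in knockout HSC 1 may hide a loss there, so lower capture stays open. A direct effect of Tet2 on histone transcripts is a candidate explanation that these libraries cannot test further.

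Libraries mixed cells of both sexes. Male-marked cells made up 25.1% and 42.7% of marked cells in control HSC, 25.5% and 68.5% in control MPP3, 99.8% and 35.2% in knockout HSC, and 99.9% and 25.1% in knockout MPP3. In the 6 libraries with both, 28 of 13470 genes differed between male-marked and female-marked cells, 8 higher in male and 20 in female cells. Apart from Xist, Tsix and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, 22 genes passed. On the X, Kdm6a (-0.73, male minus female), Jpx (-0.62), Eif2s3x (-0.52) and Kdm5c (-0.40) were higher in female cells, genes known to escape X inactivation or lie at its centre. Of 15 autosomal genes, Klf9 was at -0.17, and 7 lay on chromosome 18: Dctn4 (-0.32), Gm4841 (0.69), Pqlc1 (0.28), Txnl4a (0.23), 1500015A07Rik (0.34), F830016B08Rik (-0.71) and Gm4951 (-0.66).

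Among autosomal genes tested, 344 of 13001 lie on chromosome 18, so 0.397 of the 15 would be expected there (odds ratio 32.8, Fisher's exact p = 4.58e-08, two-sided). This is consistent with male and female donors that carried different haplotypes of chromosome 18, which could differ in expression without any effect of sex. X-linked genes were left out, since they differ by sex itself. The real assignment of sex marks then called 15 autosomal genes and the highest of the others 0. As 1 of 32 assignments is the smallest possible share, chance is not excluded for the set. Nor is chance excluded for single genes, as 21 unchanged genes were called beside 200 changed ones in simulated data. The donors are not described in the labels, and no genotype was read from the sequences.

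Between the genotypes edgeR over the 8 libraries, with its low-count filter and no block, called no gene in HSC or MPP3, and DESeq2 called 12 and 20. Slpi was chosen after its value was seen. This secreted inhibitor of elastase had 34.8 and 23.6 CPM in control HSC and 4.59 and 4.49 CPM in knockout HSC, and DESeq2 gave a log2 fold change of -2.70 (adjusted p = 1.17e-10). With edgeR it was at -2.69 (SE 0.40, adjusted p = 0.811), without the filter at -2.67 (adjusted p = 0.000103), and with the 4 HSC libraries alone at -2.66 (adjusted p = 0.0470).

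Some clusters came mostly from single libraries. Cluster 13 held 2208 of its 2448 cells from control MPP3 1, cluster 6, led by histone genes, 567 of 797 from the same library, cluster 8 1327 of 1426 from knockout HSC 2, and cluster 2 539 and 286 of 844 from control MPP3 1 and control HSC 1. The difference between replicates 1 and 2 of a group was correlated across genes between groups: 0.580 between control HSC and control MPP3 and 0.306 between knockout HSC and knockout MPP3, against -0.101 to 0.344 between the other pairs of groups.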
